A study of Arabidopsis thaliana with 60 samples.

How the data were processed

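Leaf RNA of Arabidopsis thaliana had been measured on 60 single-colour arrays, 3 for each of 20 groups. The deposited values are one intensity per probe set, MAS5 signal on a linear scale, which the authors made with the MAS5 software per the submitters' processing notes. The version and settings of MAS5 are not given in the sources used here. On every array the mean of the values left after trimming 2% at each end was 100, so the arrays share a common scale. The median signal per array ran from 32.2 to 40.0, and the 3'-to-5' signal ratio of the GAPDH control probe sets from 0.824 to 3.23. The same ratio ran from 1.76 to 14.4 for the actin and from 1.58 to 5.84 for the ubiquitin control probe sets, and the signal of the 25S rRNA control from 33.2 to 2690.

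Groups came from the labels. The labels of the first array of set 14 disagree, since its tissue field gives leaf 4 and the other arrays of the set leaf 6. It was kept with rosette leaf 6. Its lowest r to the other arrays of that set was 0.986 and its highest to rosette leaf 4 was 0.979, and an alternative moved it. The labels do not state that arrays of a group came from separate plants, so p-values measure only the spread between these samples, which may be technical. The arrays were taken as unpaired.

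Of 22810 probe sets, 64 controls were left out. Values were taken as log2(value + 6.139), the pseudocount being the median over arrays of each array's 20th percentile, so a fold change is on that scale and understates the change of dim genes. The 15809 probe sets above the 40th percentile of their own array on all arrays of at least 1 group were tested. Linear models were fitted to all 20 groups together with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and an intensity trend, on 40 residual degrees of freedom. A probe set was called at a Benjamini-Hochberg adjusted p below 0.05 and an absolute log2 difference of at least 1. No further normalization was applied. The leaf position trend was a linear contrast of the means of leaves 2, 4, 6, 8, 10 and 12 on leaf number, given as the fitted difference between leaf 12 and leaf 2. Senescing and cauline leaves were compared with the mean of these 6 groups, and the petiole with the mean of both blade parts.

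Gene names came from the array's annotation as supplied. It gave 1 gene for 13513 probe sets and several for 503, and 8730 probe sets were not in it and stay unnamed. No gene was named from a probe set with several, and 8620 named probe sets were tested. Gene lists were fixed before the data were examined, with 502 genes, of which 77 had a named probe set. A further 17 lists were assembled from the named genes after the annotation had been seen and before any comparison was computed. These are the lists of cell division, nuclear chloroplast function, plastid- and mitochondrion-encoded genes, wall-modifying genes, UDP-glycosyltransferases, proteases, cold and dehydration, sugar transporters, trichome development, leaf shape and marginal growth and immune signalling, and others the text does not name. Lists with at least 3 measured members, 30 in all, were tested in the 13 comparisons with camera in limma at a correlation of 0.01, adjusted over all 390 tests. Of these 93 passed, and 46 passed with an estimated correlation. The text gives every list that passed both ways and part of those that passed only at 0.01.

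Named genes were chosen by a rule fixed before the data were examined. Per comparison it took the 5 largest increases and 5 largest decreases among called, named probe sets whose groups did not overlap and whose brighter group lay above the 60th percentile, and up to 4 called members of each list. Genes given as the largest or lowest of a comparison are so among the probe sets that met these conditions, and unnamed probe sets could not be chosen. The code for this rule was corrected once to follow its wording, after a first run and before any gene it chose had been looked at. The text gives most of the genes so chosen and leaves out others, a selection made after their values had been seen. Further genes of the same tables stand beside them where the overlap of the gl1T comparisons or a level in every group is described, chosen after their values had been seen. The code was tested on simulated data after a first fit to the deposited values had been made, and was not changed by it. With 100 genes simulated at a log2 difference of 1.5 among the 15809 of the gl1T comparison in leaf 4, 98 were recovered, and all 100 at 2. Alternatives were a pseudocount of 1 or 4 times larger, no filter or a filter at the 60th percentile, quantile normalization, array weights, a replicate block, only the compared groups, other partner groups, the plain difference of leaf 12 and leaf 2 for the trend, the moved array and each array left out in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.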

Results

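The data were 60 arrays of the Arabidopsis thaliana leaf, from seed leaves to senescing leaves, in 20 groups of 3. The arrays carried 22810 probe sets, of which 15809 were bright enough to be tested. Most groups came from the accession Col-0 grown on soil in continuous light at 23 °C. They were the cotyledons, leaves 1 and 2, leaf 4 at 1 cm, rosette leaves 2, 4, 6, 8, 10 and 12, the petiole and the proximal and distal parts of the blade of leaf 7, senescing leaves and cauline leaves, which sit on the flowering stem. A line labelled gl1T gave leaf 4 at 1 cm and leaf 12. In addition, 3 sets of vegetative rosettes grew in 10 h of light at 22 °C, and leaves came from plants on medium with 1% sucrose. In the following, numbers after gene names are log2 differences ± SE from the limma fit, and signals are means ± SD (n = 3 arrays). A gene rose or fell where the adjusted p was below 0.05 and the difference at least 1 on the log2 scale. Arrays of a group correlated with r of 0.981 to 0.992, and the number of arrays limits the precision.

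Across rosette leaves 2 to 12 of Col-0, genes of cell division and chlorophyll synthesis rose towards the youngest leaf, and several anthocyanin genes fell. The fitted span from leaf 2 to leaf 12 was highest for AT4G29020 (5.92 ± 0.085), AT2G33850 (5.77 ± 0.18), AT1G11850 (5.65 ± 0.14), AT5G48490 (5.11 ± 0.09) and AT1G31690 (4.87 ± 0.091). At the other end stood AT1G76960 (-5.87 ± 0.13), AT2G37130 (-5.33 ± 0.17), CML41 (AT3G50770, -5.03 ± 0.14), a calmodulin-like protein, AT4G14020 (-5.02 ± 0.13) and AT4G01390 (-4.54 ± 0.19). Of 24 measured genes of cell division, 17 rose (camera adjusted p = 1.89e-06). Among them were the DNA topoisomerase TOPII (AT3G23890, 2.60 ± 0.20), the histone HTB2 (AT5G22880, 2.25 ± 0.084), the replication licensing factor PRL (AT4G02060, 2.11 ± 0.10) and the Aurora kinase AUR1 (AT4G32830, 2.09 ± 0.098). The cell cycle genes listed before the data were examined rose in 4 of 4 measured cases (4 adjusted over the list alone, camera adjusted p = 0.00974, but adjusted p = 0.108 with an estimated correlation), with AUR2 (AT2G25880, 1.94 ± 0.13) and AUR3 (AT2G45490, 1.31 ± 0.16) beside PRL and AUR1. Chlorophyll synthesis rose in 3 of 4 genes (3 adjusted over the list alone, camera adjusted p = 0.00247): the protochlorophyllide oxidoreductase PORB (AT4G27440, 1.80 ± 0.076), GSA1 (AT5G63570, 1.53 ± 0.069) and HEMB1 (AT1G69740, 1.25 ± 0.043), both of the tetrapyrrole pathway. Nuclear genes of chloroplast function rose in 8 of 26 cases and fell in 1 (camera adjusted p = 0.00239). Called members were the uroporphyrinogen decarboxylases HEME1 (AT3G14930, 2.38 ± 0.074) and HEME2 (AT2G40490, 1.69 ± 0.068) and the magnesium chelatase subunit CHLI2 (AT5G45930, 1.80 ± 0.081).

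The stomatal lineage factors SPCH (AT5G53210, 2.27 ± 0.20) and FMA (AT3G24140, 1.12 ± 0.10) rose (2 of 2 measured members, 2 adjusted over the list alone), as did the MADS-box factors AGL24 (AT4G24540, 3.04 ± 0.16) and AGL42 (AT5G62165, 2.80 ± 0.19), 2 of 3 measured flowering genes (2 adjusted over the list alone, camera adjusted p = 0.177). SPCH signal was 1.61 ± 0.620 in leaf 2 and 33.4 ± 5.53 in leaf 12, and that of AGL42 7.18 ± 2.29 and 92.8 ± 11.8. The AP2-like flowering repressor SNZ (AT2G39250, -1.12 ± 0.14) fell, 1 of 2 measured members of its list (1 adjusted over the list alone). The cytokinin response regulator ARR15 (AT1G74890, 1.80 ± 0.18), the trichome factors ATMYC1 (AT4G00480, 1.64 ± 0.13) and GIS (AT3G58070, 1.08 ± 0.12) and the thionin gene THI2.1 (AT1G72260, 3.07 ± 0.17) rose. Of the trichome regulators 1 of 4 rose (1 adjusted over the list alone, camera adjusted p = 0.415), and of the trichome development genes 2 of 8 (camera adjusted p = 0.123). The lists of leaf polarity (3 measured, camera adjusted p = 0.638) and of leaf shape and marginal growth (11 measured, camera adjusted p = 0.477) did not pass. The defensin gene PDF1.2 (AT5G44420, -3.89 ± 0.12) and BCAT4 (AT3G19710, -2.94 ± 0.077), of methionine-derived glucosinolate synthesis, fell. Anthocyanin genes fell in 3 of 4 cases (3 adjusted over the list alone, camera adjusted p = 0.0382, but adjusted p = 0.124 with an estimated correlation): the dihydroflavonol reductase DFR (AT5G42800, -2.31 ± 0.15) and the glycosyltransferases UF3GT (AT5G54060, -1.96 ± 0.12) and AT4G14090 (-2.24 ± 0.19). The sugar exporters SAG29 (AT5G13170, -3.93 ± 0.23), SWEET11 (AT3G48740, -1.93 ± 0.053) and SWEET13 (AT5G50800, -1.53 ± 0.14), the vacuolar processing enzyme GAMMA-VPE (AT4G32940, -3.60 ± 0.057) and the cold-regulated COR15A (AT2G42540, -2.91 ± 0.097) fell as well. Of 16 measured proteases 4 rose and 6 fell (camera adjusted p = 0.779), the subtilases SBT1.3 (AT5G51750, 3.89 ± 0.098) and SBTI1.1 (AT1G01900, 3.54 ± 0.16) being among the rising ones.

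limma called 3642 probe sets along the leaf positions, 1836 rising and 1806 falling, and 2392 with a pseudocount 4 times larger. The labels of leaves 2 to 12 state that leaf 12 was about 1 cm long, so leaf number and leaf size run together in this trend.

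**Figure D1:**
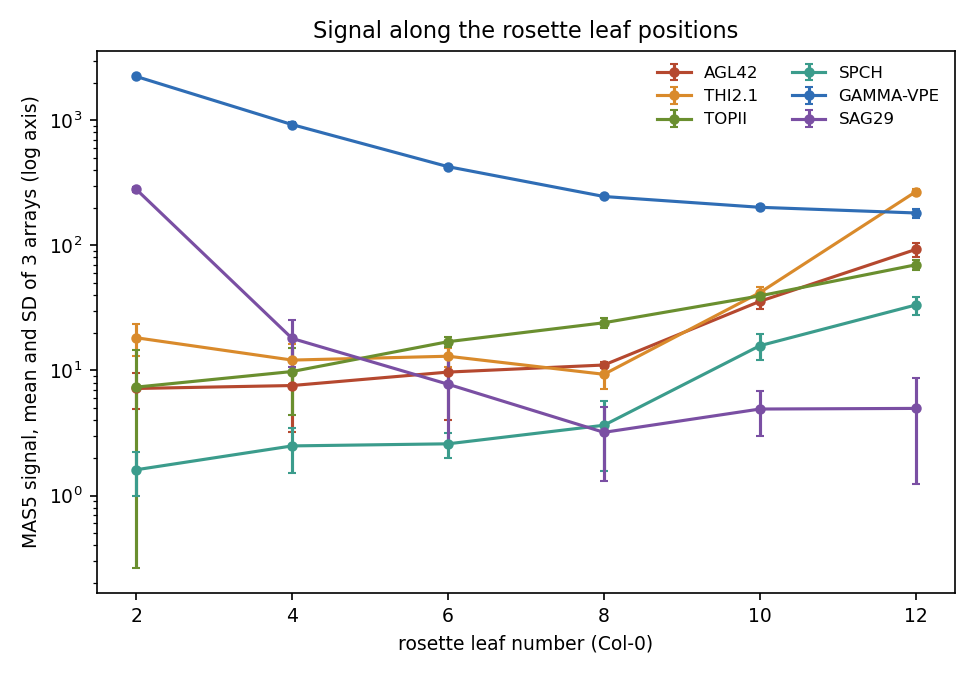
MAS5 signal (log axis) of 6 genes against rosette leaf number in Col-0, with points for the mean and bars for the SD of 3 arrays. AGL42, THI2.1, TOPII and SPCH were highest in leaf 12 (SPCH 33.4 ± 5.53), and GAMMA-VPE and SAG29 in leaf 2 (SAG29 281 ± 11.7).

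Senescing leaves were compared with the mean of the rosette leaves 2 to 12. Nuclear genes of chloroplast function fell and genes of anthocyanin synthesis rose. All 5 measured photosystem genes fell (5 adjusted over the list alone, camera adjusted p = 0.00195, but adjusted p = 0.144 with an estimated correlation). These included PSAN (AT5G64040, -2.85 ± 0.073), PSAE-1 (AT4G28750, -2.61 ± 0.086), PSBY (AT1G67740, -2.02 ± 0.056) and the light-harvesting protein LHCB4.1 (AT5G01530, -1.89 ± 0.063). Of 26 nuclear genes of chloroplast function, 20 fell (camera adjusted p = 3.17e-09). Examples were the NDH complex subunits NdhN (AT5G58260, -3.61 ± 0.044) and NdhL (AT1G70760, -3.57 ± 0.068), CHLI2 (-3.17 ± 0.073) and the photosystem assembly factor PSB27 (AT1G03600, -3.10 ± 0.086). In the Calvin cycle 2 of 3 measured enzymes fell (2 adjusted over the list alone, camera adjusted p = 0.0299, but adjusted p = 0.257 with an estimated correlation): SBPASE (AT3G55800, -2.32 ± 0.054) and PRK (AT1G32060, -1.92 ± 0.051). Chlorophyll synthesis fell in 3 of 4 genes (3 adjusted over the list alone, camera adjusted p = 0.00247). Such genes were PORB (-3.59 ± 0.069), the methyltransferase CHLM (AT4G25080, -3.35 ± 0.046) and HEMB1 (-1.91 ± 0.039). Wall-modifying genes, a list of expansins and xyloglucan-modifying enzymes that also holds EXO, which is neither, fell in 11 and rose in 1 of 18 cases (camera adjusted p = 4.84e-05). They included EXO (AT4G08950, -6.31 ± 0.054), EXLA1 (AT3G45970, -5.27 ± 0.064), EXPA8 (AT2G40610, -3.50 ± 0.10) and XTH18 (AT4G30280, -3.42 ± 0.19). Cell division genes fell in 9 of 24 cases (camera adjusted p = 0.00876). Among them were PRL (a fold of 4.29 downwards with a log2 SE of 0.094), HTB2 (-2.02 ± 0.076) and TOPII (-1.69 ± 0.18). The rosette mean includes leaf 12, towards which 17 of these 24 genes rose. How far the fall of the list depends on that partner was not tested. Of 33 plastid-encoded photosynthesis genes 2 rose and 2 fell (camera adjusted p = 0.0750), and of 10 plastid-encoded NDH genes 1 rose and 1 fell (camera adjusted p = 0.440). Plastid-encoded genes of gene expression were mixed, 2 rising and 7 falling of 20 (camera adjusted p = 0.0229, but adjusted p = 0.662 with an estimated correlation).

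Anthocyanin genes rose in 4 of 4 measured cases in the senescing leaves (4 adjusted over the list alone, camera adjusted p = 0.00406): AT4G14090 (5.42 ± 0.17), UF3GT (4.87 ± 0.10), DFR (4.49 ± 0.14) and UGT78D2 (AT5G17050, 2.75 ± 0.091). UF3GT signal was 1123 ± 109 in senescing leaves and 171 ± 9.92 in rosette leaf 2. Autophagy genes rose in 7 of 9 cases (7 adjusted over the list alone, camera adjusted p = 0.00461, but adjusted p = 0.0851 with an estimated correlation). Called members were ATG8B (AT4G04620, 2.47 ± 0.092), APG8A (AT4G21980, a fold of 4.29 with a log2 SE of 0.10), ATG8H (AT3G06420, 1.57 ± 0.13) and ATG3 (AT5G61500, 1.53 ± 0.064). Of the senescence genes 3 of 5 rose (3 adjusted over the list alone, camera adjusted p = 0.0552): the transcription factors WRKY6 (AT1G62300, 2.70 ± 0.14) and WRKY53 (AT4G23810, 1.68 ± 0.064) and the transporter SAG29 (1.43 ± 0.20). Against leaf 2 alone, SAG29 was lower in the senescing leaves (-2.31). The vacuolar processing enzymes GAMMA-VPE (3.45 ± 0.051) and BETA-VPE (AT1G62710, 3.18 ± 0.12), the subtilases SBT3.3 (AT1G32960, 2.83 ± 0.20) and SBT3.5 (AT1G32940, 2.68 ± 0.17), the osmotin-like OSM34 (AT4G11650, 3.91 ± 0.22), the auxin-conjugating enzyme WES1 (AT4G27260, 2.45 ± 0.092) and the clock gene GI (AT1G22770, 2.07 ± 0.091) also rose. The protease list did not pass, as 6 of 16 rose and 5 fell (camera adjusted p = 0.739). UDP-glycosyltransferases rose in 11 and fell in 2 of 27 cases (camera adjusted p = 0.0379, but adjusted p = 0.165 with an estimated correlation). These included UGT73B5 (AT2G15480, 3.83 ± 0.18) and UGT72E1 (AT3G50740, 2.95 ± 0.098). The polarity genes YAB3 (AT4G00180, -1.77 ± 0.077) and YAB5 (AT2G26580, -1.36 ± 0.099) fell while PHV (AT1G30490, a fold of 2.46 with a log2 SE of 0.12) rose (3 adjusted over the list alone, camera adjusted p = 0.545), and the defensin PDF1.2 (-3.07 ± 0.10) fell. The largest shifts upwards were those of AT5G39520 (6.41 ± 0.18), AT1G62760 (5.97 ± 0.22), AT3G61930 (5.59 ± 0.19) and AT2G25625 (5.55 ± 0.16). Downwards they were those of AT1G29670 (-7.61 ± 0.055), AT2G10940 (-6.92 ± 0.073), EXO (given above), AT3G10720 (-6.20 ± 0.05) and AT5G44020 (-6.05 ± 0.06).

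In this comparison limma called 5227 probe sets, 2594 higher and 2633 lower in senescing leaves. On the senescing arrays the 100 brightest probe sets held 8.77 ± 0.19% of all signal (SD, n = 3), and group means of this share elsewhere ran from 10.8% to 13.3%. Against leaf 2 alone 3615 probe sets were called.

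Cauline leaves were set against the same rosette leaves. AGL42 (3.36 ± 0.17) and the flowering bZIP factor FD (AT4G35900, 1.08 ± 0.23) rose, 2 of 3 measured flowering genes (2 adjusted over the list alone, camera adjusted p = 0.563). The trichome repressor TRY (AT5G53200, a fold of 2.83 with a log2 SE of 0.16), 1 of 4 measured trichome regulators (1 adjusted over the list alone, camera adjusted p = 0.965), GAMMA-VPE (3.29 ± 0.051), the sugar exporters SWEET13 (2.07 ± 0.13) and SWEET11 (a fold of 2.30 with a log2 SE of 0.048), the auxin synthesis gene YUC6 (AT5G25620, 1.45 ± 0.28) and WRKY6 (1.73 ± 0.14) rose. Autophagy genes rose in 3 of 9 cases (3 adjusted over the list alone, camera adjusted p = 0.00406, but adjusted p = 0.0819 with an estimated correlation): ATG8B (1.65 ± 0.092), APG8A (1.17 ± 0.10) and ATG8F (AT4G16520, 1.02 ± 0.046). Wall-modifying genes fell in 9 and rose in 3 of 18 cases (camera adjusted p = 0.00974, but adjusted p = 0.0660 with an estimated correlation), with EXO (-3.24 ± 0.054), XTH18 (-2.99 ± 0.19) and EXLA1 (-2.75 ± 0.064) down and EXPA16 (AT3G55500, 2.99 ± 0.10) and EXPA8 (1.95 ± 0.10) up. Cell division genes fell in 6 of 24 cases (camera adjusted p = 0.00382). Examples were HTB2 (-1.63 ± 0.076) and PRL (-1.36 ± 0.094). The mean of the rosette leaves includes leaf 12, towards which 17 of these 24 genes rose. TOPII, lower against that mean, stood at 0.00489 against leaf 2 alone. Nuclear chloroplast genes fell in 3 of 26 cases (camera adjusted p = 0.00681). UDP-glycosyltransferases rose in 9 of 27 cases (camera adjusted p = 0.0299, but adjusted p = 0.150 with an estimated correlation). Such genes were UGT71B6 (AT3G21780, 2.16 ± 0.20) and UGT73B5 (2.11 ± 0.18). DFR (-2.33 ± 0.14), COR15A (-2.49 ± 0.087), SAG29 (-1.28 ± 0.20) and SWEET17 (AT4G15920, -2.20 ± 0.069) fell. AT3G62960 (4.77 ± 0.14), AT1G64360 (4.46 ± 0.18) and AT2G47880 (4.08 ± 0.11) rose most and AT5G05250 (-4.23 ± 0.14), AT1G47400 (-4.06 ± 0.14), AT1G49500 (-3.68 ± 0.07) and the methionine sulfoxide reductase MSRB6 (AT4G04840, -3.57 ± 0.072) fell most. The test called 2313 probe sets, 1120 higher and 1193 lower. The count was 1477 against leaf 2 alone, 4467 against leaf 12 alone and 1456 with a pseudocount 4 times larger. Of the 2313 probe sets, 917 were also called in the same direction against leaf 2 alone. GAMMA-VPE, SWEET13 and SWEET11 fell towards leaf 12 along the rosette, and the mean includes leaf 12. Against leaf 2 alone CML41, which rose against the mean (1.35 ± 0.12), was lower (-2.02).

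The line gl1T was compared with Col-0 in leaf 4 at 1 cm and in leaf 12. A length of about 1 cm is labelled for Col-0 leaf 12 and none for gl1T leaf 12. The labels say no more of the line than its name. No probe set used here carries the name of GL1, a trichome-initiating factor, so GL1 was not analysed here and the line labels were not checked by it. In leaf 4, genes of rapid defence and stress signalling were higher in gl1T: 10 of 21 measured immune signalling genes rose (camera adjusted p = 6.29e-13). They included the zinc finger factor STZ (AT1G27730, 3.44 ± 0.085), the calmodulin-like CML38 (AT1G76650, 3.08 ± 0.13) and CML37 (AT5G42380, 2.45 ± 0.19), WRKY53 (2.63 ± 0.084) and the AP2/ERF factor ORA47 (AT1G74930, 2.02 ± 0.10). STZ was also the only measured member, of 9, of the list of touch, wound and heat handling fixed in advance (1 adjusted over the list alone). STZ signal was 812 ± 25.3 in gl1T and 69.7 ± 7.47 in Col-0. AT3G10930 (3.42 ± 0.20), AT1G76960 (3.28 ± 0.15), the defensin PDF1.2b (AT2G26020, 3.19 ± 0.20), ZCF37 (AT1G59590, 3.16 ± 0.17) and PDF1.2 (1.75 ± 0.14) rose too, as did the glutaredoxin GRX480 (AT1G28480, 1.58 ± 0.12), the auxin-conjugating GH3.3 (AT2G23170, a fold of 2.83 with a log2 SE of 0.17), EXLA1 (1.72 ± 0.084) and EXPA8 (1.09 ± 0.13). Anthocyanin genes fell in 3 of 4 cases (3 adjusted over the list alone, camera adjusted p = 0.00406): AT4G14090 (-1.57 ± 0.22), DFR (-1.17 ± 0.18) and UGT78D2 (-1.01 ± 0.12). SPCH (-1.72 ± 0.24), the beta-glucosidase PYK10 (AT3G09260, -1.76 ± 0.18), AT2G33850 (-4.46 ± 0.21), AT5G62210 (-2.01 ± 0.23) and AT5G26270 (-1.78 ± 0.11) fell. Of 5 senescence genes 2 rose (2 adjusted over the list alone, camera adjusted p = 0.0245, but adjusted p = 0.0510 with an estimated correlation), WRKY53 and SAG101 (AT5G14930, 1.14 ± 0.16). Cell division genes leaned lower in gl1T as a list (median -0.34, camera adjusted p = 0.00728). The trichome regulators as a list did not pass (camera adjusted p = 0.779, 4 measured), and TRY stood at -0.38 ± 0.20. The test called 624 probe sets, 537 higher and 87 lower in gl1T (356 with a pseudocount 4 times larger). The labels note soil in the Col-0 leaf 4 samples.

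In leaf 12 the immune signalling genes went the other way: 7 of 21 fell in gl1T (camera adjusted p = 3.17e-09). Among them were CML38 (-2.84 ± 0.13), STZ (-2.71 ± 0.085), the ubiquitin ligase PUB23 (AT2G35930, -2.51 ± 0.18) and ORA47 (-2.11 ± 0.10). STZ stood alone for the handling list here as well (1 adjusted over the list alone). STZ signal was 122 ± 16.3 in gl1T and 829 ± 58.6 in Col-0. AT2G27080 (-2.91 ± 0.21), AT1G19020 (-2.90 ± 0.16), EXLA1 (-3.61 ± 0.084), XTH18 (-2.18 ± 0.24) and EXO (-1.78 ± 0.07) fell, and wall-modifying genes fell in 5 and rose in 2 of 18 cases (camera adjusted p = 0.0299, but adjusted p = 0.124 with an estimated correlation). The alpha-expansins fixed in advance leaned higher in gl1T (3 measured, median 0.73, 1 adjusted over the list alone, camera adjusted p = 0.00509). The dehydrins COR47 (AT1G20440, -1.71 ± 0.071) and LTI30 (AT3G50970, -1.58 ± 0.13) fell while COR15A (1.22 ± 0.11) rose. TRY (1.46 ± 0.20) rose, 1 of 4 measured trichome regulators (1 adjusted over the list alone, camera adjusted p = 0.818). Anthocyanin genes rose in 2 of 4 cases (2 adjusted over the list alone, camera adjusted p = 0.00239): AT4G14090 (1.28 ± 0.22) and UF3GT (1.01 ± 0.14). AT1G76960 (4.02 ± 0.15), the chitinase gene CHI (AT2G43570, 2.83 ± 0.14), the cellulose synthase-like CSLA01 (AT4G16590, 2.26 ± 0.12), AT3G28540 (2.20 ± 0.22), the wax ester synthase WSD1 (AT5G37300, 1.88 ± 0.23), the flavonol glycosyltransferase UGT78D1 (AT1G30530, 1.51 ± 0.099), PDF1.2 (1.58 ± 0.14) and EXPA8 (1.59 ± 0.13) rose. AT2G33850 (-3.73 ± 0.21) fell. The test called 604 probe sets, 259 higher and 345 lower in gl1T (334 with a pseudocount 4 times larger). On gl1T array A the 3'-to-5' signal ratio of the GAPDH control was 3.23, against 1.34 and 1.39 on B and C, and without array A 616 probe sets were called.

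The difference between the line effects, leaf 12 minus leaf 4, was tested as an interaction. It was lowest for STZ (-6.15 ± 0.12), AT3G10930 (-6.07 ± 0.28), CML38 (-5.92 ± 0.19), AT3G02840 (-5.47 ± 0.28) and EXLA1 (-5.33 ± 0.12). Immune signalling genes were called below 0 in 15 of 21 cases (camera adjusted p = 1.56e-15), CML37 (-4.18 ± 0.27), ORA47 (-4.14 ± 0.14) and WRKY53 (-3.56 ± 0.12) among them. All 4 measured anthocyanin genes were called above 0 (4 adjusted over the list alone, camera adjusted p = 0.000207), from AT4G14090 (2.85 ± 0.32) to UF3GT (a fold of 2.83 with a log2 SE of 0.19), and so were WSD1 (3.83 ± 0.32), AT1G60590 (2.65 ± 0.17), the F-box gene AFR (AT2G24540, 2.59 ± 0.19), AT3G28220 (2.41 ± 0.20), UGT78D1 (2.32 ± 0.14), SPCH (1.99 ± 0.34) and TRY (1.83 ± 0.29). GH3.3 (-2.88 ± 0.24) and COR47 (a fold of 4.29 downwards with a log2 SE of 0.10) were below 0. Of 5 senescence genes 2 were called below 0 (2 adjusted over the list alone, camera adjusted p = 0.00728). The interaction called 1297 probe sets, 455 above and 842 below 0 (796 with a pseudocount 4 times larger). Both gl1T comparisons together, which share no arrays, called 65 probe sets in the same direction, where independent lists would give 10.7, and 193 in opposite directions, where they would give 13.1. Same-direction genes included AT1G76960, CHI, PDF1.2, PDF1.2b, EXPA8 and the pyruvate phosphate dikinase PPDK (AT4G15530), all higher in gl1T, with PPDK at 1.09 in leaf 4 and 1.23 in leaf 12. AT2G33850, AT5G26270 (-1.78 and -2.67) and the pectin methylesterase PME61 (AT3G59010, -1.27 and -1.92) were lower in gl1T in both leaves.

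**Figure D2:**
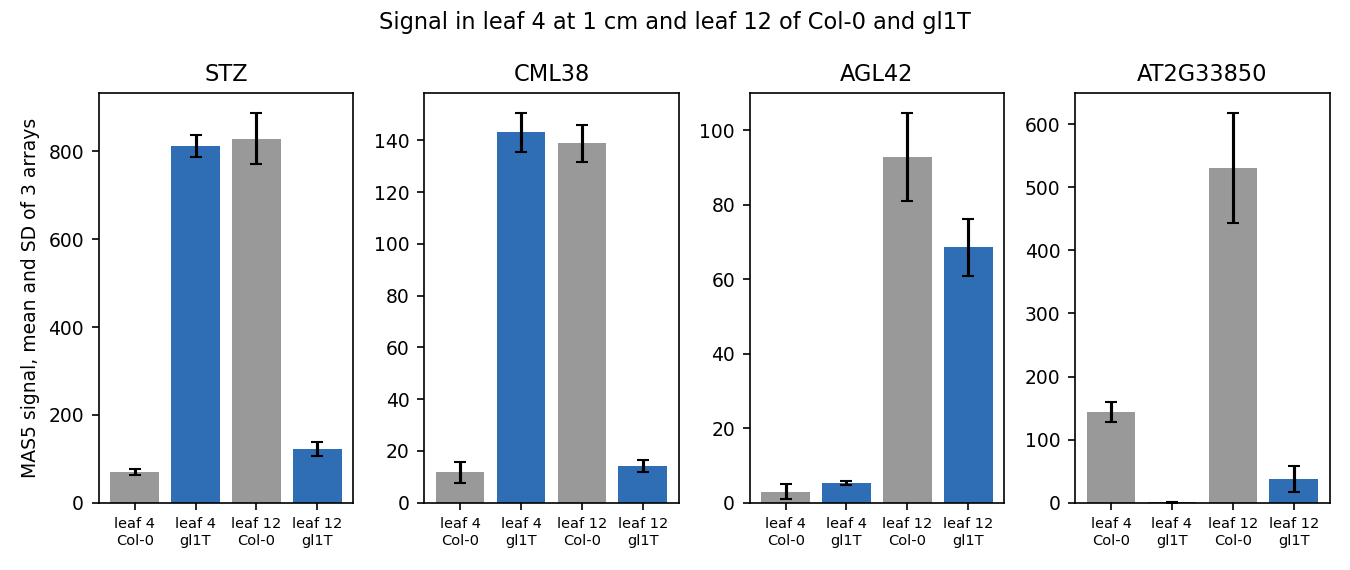
MAS5 signal of STZ, CML38, AGL42 and AT2G33850 in leaf 4 at 1 cm and leaf 12 of Col-0 (grey) and gl1T (blue), with bars for the mean and error bars for the SD of 3 arrays. STZ was 812 ± 25.3 in gl1T leaf 4 and 122 ± 16.3 in gl1T leaf 12, and AT2G33850 was lower in gl1T in both leaves.

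Within leaf 7 the petiole was compared with the mean of the proximal and distal parts of the blade. AT4G39675 (3.96 ± 0.23), AT1G31710 (3.41 ± 0.14), AT1G69080 (3.33 ± 0.23), the tubulin gene TUB1 (AT1G75780, 3.16 ± 0.11) and the jacalin lectin JAL23 (AT2G39330, 2.93 ± 0.13) were highest in the petiole, and AT1G76960 (-3.97 ± 0.13), AT1G13470 (-2.85 ± 0.13), AT1G66100 (-2.64 ± 0.082), AT1G23130 (-2.62 ± 0.068) and the sucrose exporter SWEET11 (-2.61 ± 0.054) were lowest. Cell division genes rose in 5 of 24 cases (camera adjusted p = 0.000393). Called members were BUB3.2 (AT1G49910, 1.24 ± 0.20), TOPII (1.15 ± 0.21) and AUR1 (1.10 ± 0.10), the only one of 4 listed cell cycle genes called (1 adjusted over the list alone, camera adjusted p = 0.0349, but adjusted p = 0.177 with an estimated correlation). Anthocyanin genes rose in 3 of 4 cases (3 adjusted over the list alone, camera adjusted p = 0.00974): DFR (2.02 ± 0.16), AT4G14090 (1.69 ± 0.19) and UF3GT (1.38 ± 0.12). Proteases rose in 6 of 16 cases (camera adjusted p = 0.194). These included SBTI1.1 (1.78 ± 0.16) and scpl35 (AT5G08260, 1.31 ± 0.078). AGL24 (1.49 ± 0.17), the drought-induced DI21 (AT4G15910, 2.45 ± 0.13) and the wall enzymes XTH32 (AT2G36870, 1.93 ± 0.095) and EXPB3 (AT4G28250, 1.66 ± 0.092) rose. The marginal growth regulators NGA1 (AT2G46870, -1.66 ± 0.14) and NGA2 (AT3G61970, -1.05 ± 0.13) fell, as did TRY (-1.01 ± 0.18), WRKY53 (-1.28 ± 0.073), WRKY6 (-1.14 ± 0.16) and the auxin-related GH3.3 (-1.23 ± 0.15) and IAA29 (AT4G32280, -1.06 ± 0.16). Nuclear chloroplast genes fell in 2 of 26 cases, with a lower list as a whole (camera adjusted p = 1.09e-07), NdhL (-1.10 ± 0.077) and PIFI (AT3G15840, -1.08 ± 0.059) being called. Immune signalling genes fell in 2 of 21 cases (camera adjusted p = 0.00589) and senescence genes in 2 of 5 (2 adjusted over the list alone, camera adjusted p = 0.0216), and aliphatic glucosinolate genes leaned higher as a list (median 0.85, camera adjusted p = 0.00681). The test called 1095 probe sets, 650 higher and 445 lower in the petiole (529 with a pseudocount 4 times larger).

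Between the distal and proximal parts of the blade the differences were smaller. AT1G64360 (1.90 ± 0.23), the chitinase gene CHI (1.53 ± 0.14), AT4G12490 (1.38 ± 0.18), AT4G14020 (1.19 ± 0.16), AT1G62510 (1.15 ± 0.16), CML41 (1.09 ± 0.16) and UGT73D1 (AT3G53150, 1.09 ± 0.24) were higher in the distal part. AT1G31690 (-1.92 ± 0.22 and -1.74 ± 0.11 on its probe sets), AT4G29020 (-1.68 ± 0.10), AT1G31710 (-1.56 ± 0.16), AT1G11850 (-1.55 ± 0.17) and the subtilase SBTI1.1 (-1.24 ± 0.19) were lower there. Immune signalling genes leaned to the distal part as a list (camera adjusted p = 0.00481), though CML41 was the only one of 21 called. Cell division genes (median -0.19, camera adjusted p = 0.0194) and nuclear chloroplast genes (median -0.11, camera adjusted p = 0.00974) leaned lower in the distal part as lists. The test called 98 probe sets, 62 higher and 36 lower in the distal part, and 210 with a pseudocount of 1 and 24 with one 4 times larger.

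Leaves 1 and 2 were compared with the cotyledons, the seed leaves. AT5G48490 (3.45 ± 0.11), AT5G45670 (3.11 ± 0.16), AT1G11850 (3.11 ± 0.17), AT5G62210 (2.72 ± 0.23) and AT4G29020 (2.65 ± 0.10) rose most in the true leaves, while AT1G76960 (-5.22 ± 0.15), CHI (-4.92 ± 0.14), AT3G28540 (-4.19 ± 0.22), AT4G12490 (-4.15 ± 0.18) and PPDK (-4.03 ± 0.10) were lowest. Cell division genes rose in 4 of 24 cases (camera adjusted p = 0.000393). Examples were TOPII (1.35 ± 0.24), the histone HTB1 (AT1G07790, 1.23 ± 0.11) and PRL (1.07 ± 0.12), 1 of 4 listed cell cycle genes (1 adjusted over the list alone, camera adjusted p = 0.0768). HEME1 (1.38 ± 0.087), HEME2 (1.23 ± 0.08) and CHLI2 (1.22 ± 0.096) were the 3 of 26 nuclear chloroplast genes that rose (camera adjusted p = 0.00114). Immune signalling genes fell in 9 of 21 cases (camera adjusted p = 7.82e-06). Such genes were CML41 (-3.33 ± 0.16), CML37 (-2.12 ± 0.19), WRKY53 (-2.05 ± 0.084) and PUB23 (-1.89 ± 0.18). Senescence genes fell in 4 of 5 cases (4 adjusted over the list alone, camera adjusted p = 0.0661), with SAG101 (-1.37 ± 0.16), SAG29 (-1.22 ± 0.27) and WRKY6 (-1.21 ± 0.18) beside WRKY53. SWEET11 (-1.81 ± 0.062), COR15A (-1.99 ± 0.11), GAMMA-VPE (-2.41 ± 0.067) and XTH19 (AT4G30290, -3.33 ± 0.22) fell. Of 14 mitochondrial genes 5 fell (camera adjusted p = 0.00406, but adjusted p = 0.124 with an estimated correlation), cox2 (-1.69 ± 0.24) and cox1 (-1.62 ± 0.18) among them. Chlorophyll synthesis leaned higher in leaves 1 and 2 as a list (median 0.83, camera adjusted p = 0.00123). The test called 1821 probe sets, 716 higher and 1105 lower in leaves 1 and 2 (1092 with a pseudocount 4 times larger).

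Col-0 leaf 12 and leaf 4, both at about 1 cm, compared positions at like size. The leaves came from different harvests, so position cannot be told apart from harvest or plant age here. The thionin gene THI2.1 (3.95 ± 0.20), AGL42 (3.46 ± 0.22) and AGL24 (1.46 ± 0.19) were higher in leaf 12, the latter pair being 2 of 3 flowering genes (2 adjusted over the list alone, camera adjusted p = 0.0131). The AP2-like SNZ (-1.45 ± 0.17), EXPA8 (-1.82 ± 0.13) and PDF1.2 (-1.15 ± 0.14) fell, as did AT3G44450 (-2.40 ± 0.098), AT1G13650 (-2.27 ± 0.15) and AT1G20070 (-2.11 ± 0.17). Immune signalling genes rose in 9 of 21 cases (camera adjusted p = 5.7e-10): STZ (3.46 ± 0.085), CML38 (3.04 ± 0.13) and WRKY53 (2.38 ± 0.084) led. EXLA1 (2.82 ± 0.084), EXO (2.25 ± 0.07) and XTH18 (2.06 ± 0.24) rose with them. Cold and dehydration genes rose in 4 of 10 cases (camera adjusted p = 1.04e-05). They included DI21 (1.77 ± 0.15), COR27 (AT5G42900, 1.74 ± 0.097) and LTI30 (1.44 ± 0.13). Nuclear chloroplast genes, of which 8 of 26 rose towards leaf 12 along the rosette and 1 fell, leaned lower in leaf 12 here (median -0.26, camera adjusted p = 0.00195). The cell division list, of which 17 of 24 rose along the rosette, did not pass (24 measured, median 0.10, camera adjusted p = 0.714). The test called 723 probe sets, 531 higher and 192 lower in leaf 12 (448 with a pseudocount 4 times larger). The Col-0 leaf 4 arrays, whose samples carry the note of soil, also served in the gl1T comparison, so these values are not independent of those above.

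The later-harvested rosette leaf 4 was set against leaf 4 at 1 cm in Col-0. Cell division genes fell in 15 of 24 cases in the later leaf (camera adjusted p = 0.000112). Among them were HTB1 (-2.09 ± 0.11), TOPII (-1.81 ± 0.24) and PRL (-1.79 ± 0.12), and all 4 listed cell cycle genes fell (4 adjusted over the list alone, camera adjusted p = 0.0299, but adjusted p = 0.170 with an estimated correlation). SPCH (-2.60 ± 0.24) and FMA (-1.18 ± 0.12) fell (2 adjusted over the list alone), as did ARR15 (-1.86 ± 0.21), PORB (-1.34 ± 0.09), GSA1 (-1.52 ± 0.082) and HEMB1 (-1.08 ± 0.051), 3 of 4 chlorophyll synthesis genes being called lower (3 adjusted over the list alone, camera adjusted p = 0.00368). Nuclear chloroplast genes fell in 7 of 26 cases (camera adjusted p = 0.00516). Called members were HEME1 (-2.65 ± 0.087) and SAPX (AT4G08390, -1.97 ± 0.088). AT1G76960 (5.02 ± 0.15), EXLA1 (4.99 ± 0.084), PDF1.2b (4.47 ± 0.20), PDF1.2 (4.02 ± 0.14) and AT2G37130 (4.71 ± 0.21) rose, whereas AT4G29020 (-4.66 ± 0.10), AT5G48490 (-4.56 ± 0.11) and AT5G62210 (-4.54 ± 0.23) fell. Immune signalling genes rose in 12 of 21 cases (camera adjusted p = 3.02e-05). These included CML41 (3.25 ± 0.16), CML38 (3.25 ± 0.13) and STZ (3.08 ± 0.085). Autophagy genes rose in 4 of 9 cases (4 adjusted over the list alone, camera adjusted p = 0.00972, but adjusted p = 0.123 with an estimated correlation), and GAMMA-VPE (2.88 ± 0.067), COR47 (3.18 ± 0.071), COR15A (3.14 ± 0.11), GH3.3 (2.38 ± 0.17) and BCAT4 (2.45 ± 0.092) rose as well. The test called 3866 probe sets, 2033 higher and 1833 lower in the later leaf (2564 with a pseudocount 4 times larger). The note of soil on the 1 cm samples applies here too.

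The vegetative rosettes in short days came as sets 87, 89 and 90, and what distinguishes the sets is not given in the labels used. Their labels were the same but for the set number, except that set 90 had no substrate label. From set 87 to set 89, AGL24 (2.81 ± 0.19) rose and the AP2-like flowering repressor SMZ (AT3G54990, -1.44 ± 0.18) fell (1 adjusted over the list alone). AGL24 was the only one of 3 flowering genes called (1 adjusted over the list alone, camera adjusted p = 0.252). The cytochrome P450 CYP71B22 (AT3G26200, a fold of 8.00 with a log2 SE of 0.11), AT2G43590 (2.48 ± 0.18), AT5G55450 (2.23 ± 0.15), JAL23 (2.21 ± 0.15) and THI2.1 (2.01 ± 0.20) rose. AT4G15680 (-4.02 ± 0.23), AT4G15690 (-3.39 ± 0.32) and AT4G15700 (-2.90 ± 0.18), neighbouring glutaredoxin genes whose probe sets can cross-hybridise, fell, as did AT1G62290 (a fold of 8.00 downwards with a log2 SE of 0.26) and AT1G62510 (-2.98 ± 0.16). Sugar transporters fell in 3 of 9 cases (camera adjusted p = 0.000207): SWEET11 (-2.45 ± 0.062), SAG29 (-1.58 ± 0.27) and SWEET2 (AT3G14770, -1.10 ± 0.09). Wall-modifying genes fell in 5 of 18 cases (camera adjusted p = 0.00143). Examples were EXLA1 (-2.02 ± 0.084) and EXPA8 (-1.69 ± 0.13), while TOPII (1.37 ± 0.24) and KINESIN-12B (AT3G23670, 1.02 ± 0.21) were the 2 of 24 cell division genes that rose (camera adjusted p = 0.00239). Plastid-encoded photosynthesis genes had 1 of 33 called, psbA (ArthCp002, -1.17 ± 0.34) (camera adjusted p = 0.000161, but adjusted p = 0.497 with an estimated correlation). The test called 514 probe sets, 133 higher and 381 lower in set 89. The split was 282 higher and 507 lower at a pseudocount of 1 (789 in all), 40 and 208 at one 4 times larger (248), and 87 and 417 with quantile normalization. Median signal was 34.1 ± 0.551 in set 87 and 37.8 ± 0.195 in set 89, and the 100 brightest probe sets held 12.8 ± 0.332% and 10.9 ± 0.688% of the signal.

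From set 89 to set 90 the defensins PDF1.2b (2.90 ± 0.20) and PDF1.2 (2.38 ± 0.14) rose, with AT3G22240 (2.34 ± 0.13), OSM34 (1.53 ± 0.28), AT1G29270 (1.22 ± 0.26) and AGL24 (1.06 ± 0.19), again the only one of 3 flowering genes called (1 adjusted over the list alone, camera adjusted p = 0.273). SWEET11 (-1.14 ± 0.062), the methionine sulfoxide reductase MSRB5 (AT4G04830, -1.43 ± 0.10), AT4G22490 (-1.17 ± 0.17) and AT3G20370 (-1.16 ± 0.28) fell. Nuclear chloroplast genes (median -0.21, camera adjusted p = 5.7e-10) and aliphatic glucosinolate genes (median -0.40, camera adjusted p = 0.00384) leaned lower in set 90 as lists, and auxin response genes leaned higher (median 0.78, camera adjusted p = 0.00481). AGL24 signal was 1.32 ± 0.512 in set 87, 46.2 ± 4.67 in set 89 and 102 ± 3.02 in set 90, and SWEET11 signal was 888 ± 32.7, 159 ± 21.8 and a mean of 67.9. The test called 68 probe sets, 41 higher and 27 lower in set 90, with 154 at a pseudocount of 1 and 14 at one 4 times larger.

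**Figure D3:**
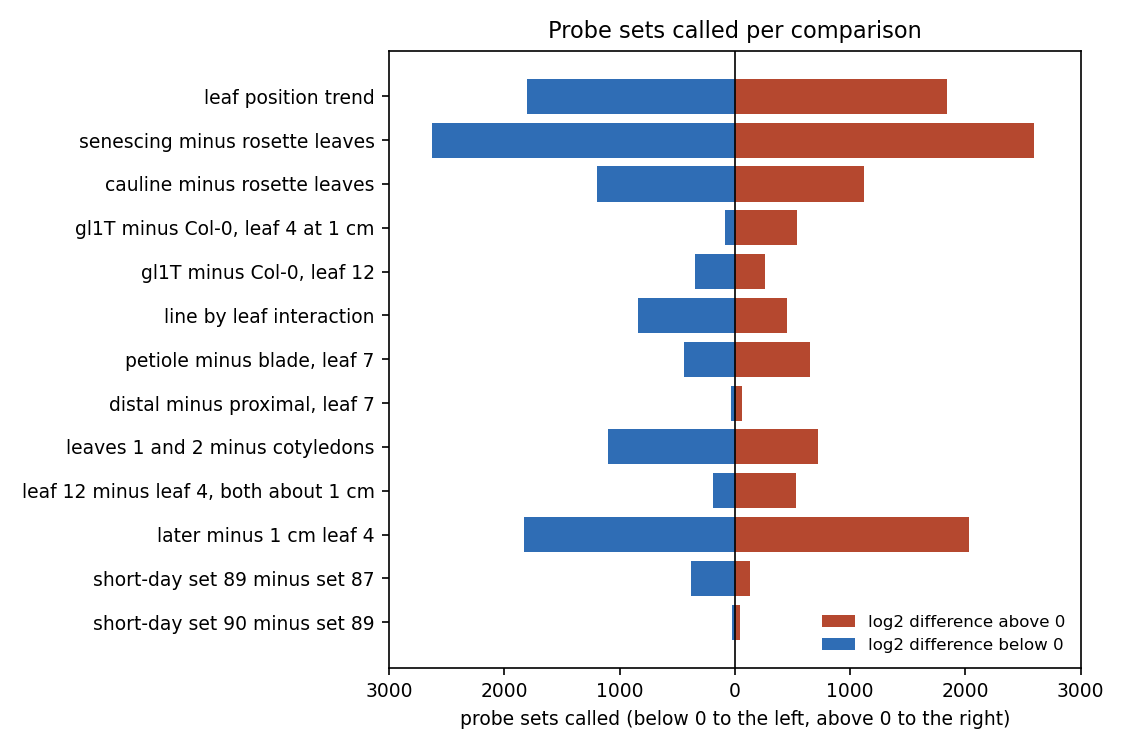
Number of probe sets called in each comparison, with bars to the right for log2 differences above 0 and to the left for those below 0. The senescing leaves gave 2594 above and 2633 below 0, and short-day sets 90 and 89 differed in 68.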

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

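The tests of label errors, of a shared line effect, of soil and of harvest were chosen only after the results had been seen. The difference of the gl1T minus Col-0 effects between leaf 12 and leaf 4 was itself tested, and its 1297 called probe sets were singled out because the difference gl1T minus Col-0 was not the same in the sets labelled leaf 4 and leaf 12. Genes with the most positive interaction were WSD1 (3.83), AT1G60590 (2.65), AFR (2.59), AT3G28220 (2.41) and UGT78D1 (2.32). The most negative were STZ (-6.15), AT3G10930 (-6.07), CML38 (-5.92), AT3G02840 (-5.47) and EXLA1 (-5.33).

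Immune signalling genes stood higher in gl1T than in Col-0 in leaf 4 and lower in leaf 12. On exchanged labels of the gl1T leaf sets the values were mixed. AGL42, the gene used for the test, argues against them, being higher in the set labelled leaf 12 by 2.71 ± 0.22, as in Col-0. THI2.1 (4.21 ± 0.203) and AGL24 (1.6 ± 0.197) were also higher in that set, as in Col-0. SNZ, lower in Col-0 leaf 12, differed little (-0.283 ± 0.175). These genes were picked after their values had been seen. Correlations of group means leaned the other way by small margins. For gl1T leaf 12, r was 0.9689 to Col-0 leaf 4 and 0.9666 to Col-0 leaf 12. For gl1T leaf 4, r was 0.9664 to Col-0 leaf 12 and 0.9634 to Col-0 leaf 4. Soil in the Col-0 leaf 4 samples cannot account for the leaf 12 part, where 7 members were called lower in gl1T and the labels note no soil. For the leaf 4 part it cannot be told apart from the set itself (median -1.13 in Col-0 leaf 4 against the rosette leaves). Without such a note, the short-day sets (-1.5) and the sucrose leaves (-1.15) were also low, but they differ in growth conditions. In the gl1T sets, themselves part of the pattern, the median was -0.91 in leaf 12 and -0.201 in leaf 4. Line labels exchanged in 1 of the leaves stay open, as the trichome development genes moved too little to decide (median -0.171 in leaf 4) and calls shared by both leaves ran both ways (65 in the same and 193 in opposite directions), and with such an exchange a line effect shared by both leaves would also give the median interaction of the immune signalling genes, -1.35, which had been seen in the comparisons themselves. A difference in harvest or in handling was not tested apart from the set. STZ is the only measured gene of the handling list fixed in advance (-6.15 in the interaction). Col-0 leaf 4 and gl1T leaf 12 were picked as the sets low in STZ. The median difference between them, 0.195 (members from -0.94 to 1.44), follows from that choice. A difference in leaf size at leaf 12, where gl1T has no labelled length, was not tested either. A line effect that depends on the leaf also remains, untested.

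Other splits of the same arrays were counted for each comparison. For the leaf position trend 1 of 100 drawn splits, the real one, gave as many as 3642 probe sets, the highest of the others being 1133. The real split was likewise alone for senescing leaves (1 of 100, 5227 against 2550), cauline leaves (1 of 100, 2313 against 1256) and the petiole (1 of 84, 1095 against 466). The splits mixed arrays of different sets, while for all 60 arrays the 2 closest arrays were of the same group. Lower counts were thus largely set in advance, and chance differences between sets are not excluded. For the interaction 2 of 100 splits gave as many, which is under 0.05, but a split that mixed leaves and lines gave 1318 against the real 1297. The other comparisons set 3 arrays against 3, and their 10 splits are too few for a share under 0.05. The highest other was 2 against 624 for gl1T leaf 4, 5 against 604 for gl1T leaf 12, 3 against 98 for the blade parts and 2 against 1821 for leaves 1 and 2. It was 4 against 723 for leaf 12 and leaf 4, 0 against 3866 for the later leaf 4, 3 against 514 for sets 89 and 87 and 5 against 68 for sets 90 and 89.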

How the results depend on the processing

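No test here was chosen after the results were seen. Of 113 counts under other settings 17 differed from the reported count by over 1.5 times, and of 129 counts with an array left out none did. With a pseudocount 4 times larger, which shrinks differences of dim genes by construction, the counts were 2392 for the trend, 1456 for cauline leaves, 356 and 334 for gl1T in leaf 4 and leaf 12, 796 for the interaction, 529 for the petiole, 24 for the blade parts, 1092 for leaves 1 and 2, 448 for leaf 12 against leaf 4, 2564 for the later leaf 4, 248 for set 89 against 87 and 14 for set 90 against 89. A pseudocount of 1, which widens them by construction, gave 210 for the blade parts, 789 for set 89 and 154 for set 90. Cauline leaves gave 1477 against leaf 2 alone, of which 917 were among those reported, and 4467 against leaf 12 alone, and the cause was not tested. Of 93 list tests that passed, 46 did with an estimated correlation. Of 5944 gene values 5622 kept their direction and side of the threshold, 314 kept the direction only and 8 reversed, each against leaf 2 alone. In senescing leaves these were SAG29 (-2.31), AGL24 (1.56) and CML41 (-0.528), and in cauline leaves TOPII (0.00489), LEA4-5 (-0.388), UGT85A4 (-0.137), CML41 (-2.02) and BSMT1 (-0.208), and the cause was not tested. The replicate letter as a replicate block gave 3642, 5227, 2313, 623, 604, 1295, 1095, 98, 1821, 723, 3866, 514 and 72 calls, in the order of the comparisons in the plot of counts, and changed none by over 1.5 times. Whether the letters pair the arrays was not settled. At most 3 of 2 to 63 same-letter pairs per comparison correlated above 0.1. For the blade parts, leaves 1 and 2 and set 89, however, each array correlated best with its own letter, as did 5 of 6 for gl1T leaf 12. The replicate block fitted the same letter effect in all groups, so it does not test pairing within a comparison. The filter at the 40th percentile of each array limited the tests to 15809 of 22746 probe sets.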

Other observations

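The test of root tissue was chosen only after the PYK10 values had been seen. Several genes, chosen after their values had been seen, had levels that set whole groups apart. Cauline leaves held the highest AGL42 signal of the 20 groups, 241 ± 17.5, against 92.8 ± 11.8 in rosette leaf 12 and 13.4 ± 2.28 in senescing leaves. THI2.1 signal was 268 ± 15.8 in Col-0 leaf 12, 315 ± 6.22 in gl1T leaf 12, and 35.2 ± 3.05 in short-day set 87 with means of 161 and 242 in sets 89 and 90, against 18.3 ± 5.15 in rosette leaf 2. AT1G76960 signal was 710 ± 119 in senescing leaves, 645 ± 193 in cauline leaves and 569 ± 74.7 in rosette leaf 2, but 1.73 ± 0.126 in Col-0 leaf 12 and 0.616 ± 0.0323 in short-day set 89. AT2G33850 took the opposite course, with 786 ± 84.7 in short-day set 90, 530 ± 87.5 in Col-0 leaf 12 and 1.90 ± 1.14 in senescing leaves. STZ, the zinc finger factor of stress responses, stood at 52.6 ± 1.31, 30.5 ± 4.34 and 49.0 ± 2.81 in short-day sets 87, 89 and 90 and at 1436 ± 15.9 in cotyledons.

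Leaves on sucrose medium had no partner group in the design and are given as values. The mean PYK10 signal there was 828, and STZ signal was 296 ± 23.6. In correlations of group means across probe sets, which are not independent replicates, the group closest to the sucrose leaves was short-day set 87 (r = 0.953). Col-0 leaf 4 at 1 cm and gl1T leaf 12 were each other's closest group (r = 0.969), and for senescing leaves the closest was the cauline leaves (r = 0.866).

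PYK10, a beta-glucosidase gene known from roots, had a signal of 2088 ± 49.9 in short-day set 87, 1396 ± 48.2 in set 89 and 888 ± 53.8 in set 90, against 11.6 ± 5.90 in rosette leaf 8 and 121 ± 26.8 in rosette leaf 2. Leaves on sucrose medium, whose tissue label is leaf, also stood above the mean of rosette leaves 2 to 12, by 4.66 ± 0.145 on the log2 scale. For the short-day sets together that difference was 5.38 ± 0.0948. Root tissue in the short-day samples may be a source of their PYK10 signal. The root-hair expansins EXPA7 and EXPA18 differed by a mean of 0.0498 on the log2 scale between short-day and rosette sets. Both lay near the floor of the arrays, so the test does not decide, and day length, temperature and set cannot be told apart in these samples.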
